A study of Caenorhabditis elegans with 2 samples.

How the data were processed

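Chromatin immunoprecipitation of GFP-FLAG-tagged DAF-16 was followed by sequencing in 2 biological replicates of whole L4 larvae, per the labels, with chromatin fragmented by sonication. A control file is listed among the inputs of the deposited peak lists. The labels name biological replicates but not how the cultures were separated. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The deposited peak lists come in 4 kinds on each of the builds ce11 and ce10. These are a list of peaks and background regions for each replicate, the same for both replicates pooled, and an optimal list thresholded by the irreproducible discovery rate (IDR), a comparison of peak ranks between replicates. Signal tracks were not used here.

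Each peak's signal is a score of the deposited narrowPeak files whose scale is not stated, ranging from 2.00 to 7975 over the ce11 lists. It was used only to rank, filter or describe peaks within a list, apart from rank and log correlations between replicates over matched peaks. The deposited −log10 q-value of each peak ended at a shared maximum, which 47.0% of the pooled ce11 peaks held, so it was not used for ranking. All 8777 IDR-thresholded peaks were among the 8777 strongest of the pooled list. Among the IDR-thresholded peaks, 100 repeated the interval of an earlier entry with a different summit, the first entry of each interval not counted. The ce11 lists were joined to the Ensembl release 115 annotation and the RefSeq sequence of the same assembly, after the chromosome lengths had been compared with the largest peak ends. The ce10 lists were used only for counts and replicate overlap, and no coordinate was converted.

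Bound means that a nuclear IDR-thresholded summit lay from 1000 bp upstream to 300 bp downstream of an annotated transcript start of a protein-coding gene. That start could lie inside the gene, as for the strongest window peaks of daf-2, smk-1, daf-3, din-1, pygl-1, eps-8, hlh-30 and skn-1. Replicate overlap and promoter location were tested with 1000 circular shifts of the summits within chromosomes, one-sided. Annotation classes were assigned in the order 5' UTR, coding exon, 3' UTR, other exon, intron, intergenic. Motifs were sought on both strands within 75 bp of the summit and in a flank centred 500 bp away on a side drawn with a fixed seed. Pairs were compared with an exact McNemar test. Gene lists (32) and motifs (9) were fixed before the data were examined, and p-values were adjusted by Benjamini and Hochberg over each family. Odds ratios carried 0.5 added to each cell, except the stratified estimate for X-linked genes and the odds ratio of motif co-occurrence. Intervals of shares are Wilson intervals at 95% and cover counting error only. They and the tests treat peaks and genes as independent, although neighbours can share a peak.

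Genes named in the report were taken from a set fixed by rule. It held the 20 strongest promoter peaks by nearest start, up to 4 bound members with the strongest peaks and up to 2 unbound members, alphabetically, of each list, and 22 genes always reported. Genes downstream in operons have annotated starts that need not be promoters, and their windows were kept. Gene names carried by several near-identical copies, among them hsp-16.1 and hsp-16.48, were counted as separate genes, and peaks there are uncertain because reads can match several copies.

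Alternatives were other overlap rules, windows, peak sets (the stronger 50%, either replicate's own strongest 8777 peaks, the pooled list), nearest starts, random lists matched on upstream gap decile, neighbouring members within 5 kb counted once, and other motif windows and controls. Stratified, family, chromosome, shared-gene and reversed-motif alternatives were added after seeing the data. On simulated data, lists of 40 genes with a true odds ratio of 1, 2 and 4 passed an unadjusted p of 0.05 in 3.5%, 52.0% and 98.0% of 200 runs over 19973 genes. A DBE put into 10% of 8748 centres was recovered as an excess of 9.87%, and 60% of shared peaks as an excess of 59.0%. Moving 40% of random peaks to gene starts gave an excess of 28.8% in promoters, less than 40% because some of the moved peaks would have lain there by chance. Lists of this size with an odds ratio of 2 were thus missed in many runs. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.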

Results

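DAF-16 is the single FOXO transcription factor of Caenorhabditis elegans, the main output of insulin-like signalling in stress resistance, dauer formation and lifespan. Its chromatin binding was measured by chromatin immunoprecipitation and sequencing in whole L4 larvae of mixed sex, from a transgenic strain in which DAF-16 carried a C-terminal GFP and FLAG tag. The series held 1 group of 2 biological replicates and no treated or mutant group, so the design asks where DAF-16 was found and how well the replicates matched, not how binding changed. The IDR-thresholded list on build ce11 held 8777 peaks, of which 8748 lay on the nuclear chromosomes and 29 on the mitochondrial genome. Replicate 1's own list held 16146 peaks and replicate 2's 21378, background regions included. The read depth of both libraries is unknown, since the files give no read counts. Signal below means the authors' own score of a peak, which ranks peaks within a list and whose scale is not stated.

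The peaks that ranked highest were found in both replicates. The strongest nuclear peak, upstream of ttr-48, a transthyretin-related gene, had a signal of 1392 in the IDR-thresholded list, 997 in replicate 1 and 401 in replicate 2. The peak upstream of dod-6, a gene named for acting downstream of DAF-16, had signals of 608 in replicate 1 and 363 in replicate 2. That of sod-3, the manganese superoxide dismutase used as a reporter of DAF-16 activity, had 124 and 91.1. The promoter peak of daf-16 itself, with a signal of 28.3 in replicate 1, had no counterpart within 100 bp in replicate 2. Of the 8777 strongest peaks of replicate 1, 5626 (64.1%, 95% Wilson interval 63.1 to 65.1) had a summit within 100 bp of one of the 8777 strongest of replicate 2, mitochondrial peaks included. After circular shifts within chromosomes the mean share was 1.91% and the highest of 1000 shifts 2.36% (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). Of the 8748 nuclear IDR-thresholded peaks, 77.3% had a summit within 100 bp in the full lists of both replicates, 98.6% in the strongest quintile by signal and 45.2% (42.8 to 47.5) in the weakest. Across the 6758 peaks matched in both, Spearman's rho of the signals was 0.74 (permutation p = 0.001, the smallest possible) and Pearson's r of their log2 values 0.68, across peaks, which are not independent replicates.

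**Figure D1:**
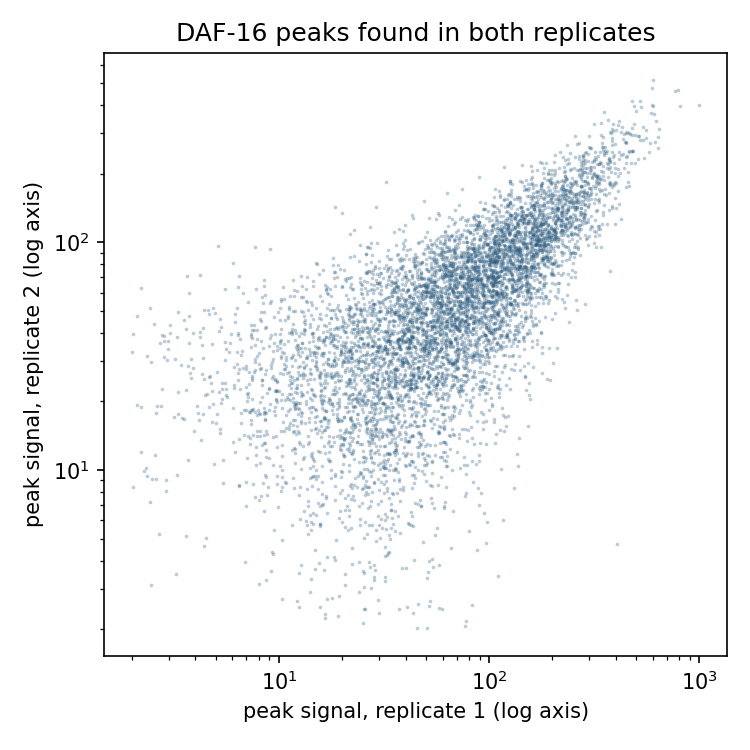
Signal of 6758 nuclear IDR-thresholded peaks in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis), each point a peak with a summit within 100 bp in both lists. Points narrow towards the strongest peaks, and Spearman's rho was 0.74.

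DAF-16 peaks lay mainly upstream of protein-coding genes. Of the 8748 nuclear summits, 4693 (53.6%, 52.6 to 54.7) fell between 1000 bp upstream and 300 bp downstream of an annotated protein-coding transcript start, against a mean of 27.7% after circular shifts (highest of 1000 shifts 29.9%, one-sided permutation p = 0.001, the smallest possible). Intergenic sequence held 60.7% of summits against 37.7% after shifts, and 5' UTRs held 4.77% against 1.79%. Coding exons held 5.98% against 24%, and introns 24.7% against 32.9% (two-sided permutation p = 0.002, the smallest possible, for each of the 4 classes). The 3' UTR share, 3.75% against 3.35%, did not pass (permutation p = 0.0519). The median distance from a summit to the nearest start was 640 bp, and 68.2% of summits were upstream of it.

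At least 1 peak lay in the promoter window of 4779 of 19973 protein-coding genes (23.9%), and 714 genes had 2 or more. Behind ttr-48, the strongest promoter peaks were that shared by H12C20.7 and the nuclear hormone receptor gene nhr-68 (signal 1249.5, summit at 11573108 of chromosome V), that of the transcription factor gene hlh-13 (signal 1199.6, summit at 4248608 of chromosome X) and that of C08E8.4 (signal 1001.4, summit at 18371779 of chromosome V). The glutathione S-transferase gene gst-29 (signal 979.8), dod-6 (954) and the galectin gene lec-6 (889) followed within the 20 strongest, which also held ttr-47 (794) and ttr-41 (784). The hlh-13, C08E8.4 and lec-6 peaks had the DAF-16 binding element GTAAACA (DBE) within 75 bp of the summit. The DAF-16 associated element CTTATCA (DAE), which contains a GATA site, stood at the C08E8.4 and lec-6 peaks as well, and at the ttr-48 peak without a DBE. A peak in the windows of several genes counted for each, as 909 peaks did. Each peak given to its nearest start alone left 3944 bound genes, and the stronger 50% of peaks left 2687.

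Genes that earlier studies placed under DAF-16 control were bound often in the class that rises with its activity. Of 39 genes on the preset class I list, 26 also stood in other lists. Of the 39, 23 were bound (59.0%, 43.4 to 72.9), against 23.9% of other genes (log2 odds ratio 2.18, adjusted exact p = 6.89e-06). They included dod-6, the aquaglyceroporin gene aqp-1 (signal 624), the lysozyme gene lys-8 (524.8) and the ferritin gene ftn-1 (487). The lysozyme gene lys-7 (426), dod-3 (339.6), the metallothionein gene mtl-1 (273), sod-3 (234), hsp-16.2 (202.5) and sip-1 (103) were bound as well, the sip-1 peak without a counterpart in replicate 1. The sod-3 summit, at 17092620 of chromosome X, lay 133 bp upstream of the start of sod-3 (WBGene00004932, 17092753 to 17094306, forward strand), in sequence annotated as an intron, with a DBE within 75 bp. The catalase genes ctl-1 and ctl-2, scl-1, old-1 and hsp-12.6 had no peak in the window. Nor had daf-15, which was also on the list. The direction in which DAF-16 changes each member was not checked here. Beyond the window, hsp-12.6 had 4 peaks within 5 kb, all past its 3' end, the strongest with a signal of 937. Within 5 kb of scl-1 lay 1 peak, just past its 3' end, with a signal of 730. Of 25 class II genes, which fall with DAF-16 activity, 10 were bound (40%, adjusted exact p = 0.118), among them cld-9 (signal 145.5), the peptide transporter gene pept-1 (131), clec-67 (127) and irg-4 (122, without a counterpart in replicate 1), but not dod-17 or clec-186. Class II passed the test with the window of 500 bp upstream to 100 bp downstream (adjusted exact p = 0.0499), with peaks given to the nearest start (0.0303), without replicate 1 (0.00101) and without replicate 2 (0.0227). All list comparisons used a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 32 lists. Lists shared genes and peaks, so their results are not independent of each other.

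Genes of the insulin/IGF-1 signalling list were bound more often than other genes, 19 of 33 (57.6%, log2 odds ratio 2.1, adjusted exact p = 7.51e-05). The list also held genes beyond the receptor and kinases of the pathway, among them daf-15, pqm-1, skn-1 and hsf-1. The log2 odds ratio was 1.5 with the window of 500 bp upstream to 100 bp downstream and 1.53 in the stronger 50% of peaks, both still passing. The strongest peaks belonged to the kinase gene akt-2 (signal 710.3), smk-1 (209, in a coding exon at an internal start), pqm-1 (209) and akt-1 (204). The insulin-like receptor gene daf-2 had a promoter peak of 101 at an internal start, and skn-1 one of 68.9, while the phosphoinositide 3-kinase subunit genes age-1 and aap-1 had none, nor had hsf-1. The dauer TGF-beta and steroid pathways had 9 of 22 bound (40.9%, adjusted exact p = 0.0994). These were led by the SMAD gene daf-3 (signal 593), daf-14 (234.6), din-1 (192) and the nuclear receptor gene daf-12 (191), all with a DBE, and daf-1 and daf-10 were not bound. Over the whole list a DBE stood at 5 of 19 promoter peaks, which did not pass against other promoter peaks (Fisher's exact test, adjusted p = 0.0993). That list passed with the stronger 50% of peaks (adjusted exact p = 0.00989), without replicate 1 (0.0308) and with nearest starts (0.0384), and against gap-matched random lists (adjusted random-list p = 0.0493). Of 33 development and seam regulators 12 were bound (36.4%, adjusted exact p = 0.122), with rnt-1 (193), daf-12, blmp-1 (168) and lin-66 (159) strongest. That list passed once genes in more than 1 list were left out (adjusted exact p = 0.0256), an alternative chosen after seeing the data.

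**Figure D2:**
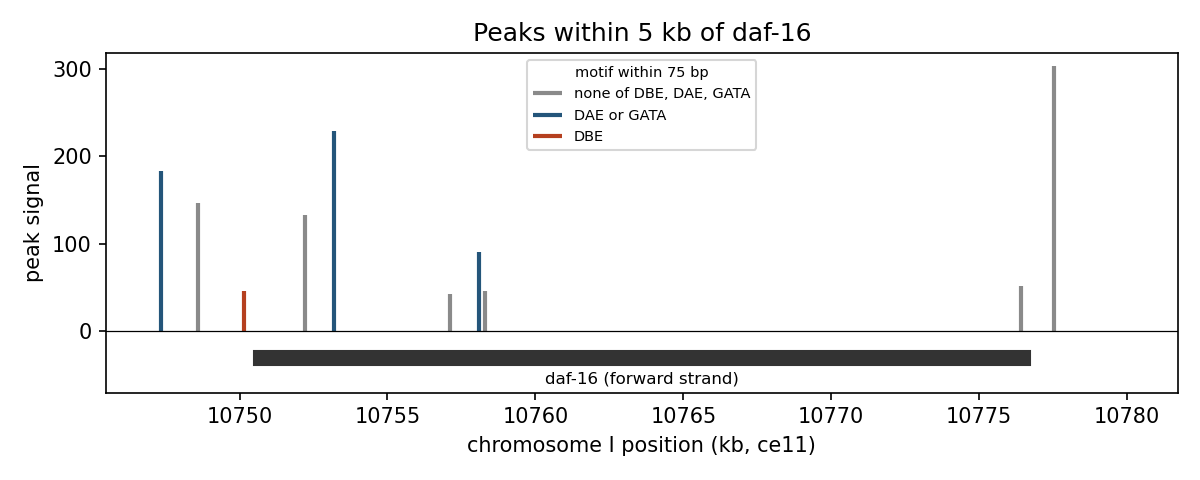
Peaks within 5 kb of daf-16 on chromosome I of ce11, each vertical line a summit with its signal as height and the motif within 75 bp as colour, and the bar the annotated gene. The promoter peak (signal 45.5) is among the lowest of 10, and the tallest (303) lies downstream of the gene.

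The daf-16 locus (WBGene00000912, chromosome I, 10750498 to 10776703, forward strand) had 10 peaks from 5 kb upstream to 5 kb downstream. The strongest, with a signal of 303 and its summit at 10777544, lay in intergenic sequence past the 3' end. An intronic peak at 10753178 had 229, and an intergenic peak 3152 bp upstream of the gene, with a DAE, had 183. The promoter peak, with its summit at 10750139, had 45.5 and a DBE. The strain carried a transgene for tagged DAF-16, and reads from it were not separated from reads of the native gene. The peaks here can therefore not be ascribed to binding at the native gene alone. No peak lay within 5 kb of unc-119, the gene mutated in the strain's background, nor of age-1, daf-15 or old-1.

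Stress, metabolic and clearance genes were bound more often than other genes. Glycolysis and gluconeogenesis had 28 of 37 bound (75.7%, log2 odds ratio 3.26, adjusted exact p = 4.85e-10), led by the glycogen synthase gene gsy-1 (signal 731), the glycogen phosphorylase gene pygl-1 (467), the glyoxylate cycle gene icl-1 (464) and the pyruvate kinase gene pyk-1 (412), but not aldo-1 or gpd-4, and gpd-2 was bound too (283). Autophagy and lysosome had 24 of 33 (72.7%, 3.04, 2.03e-08), with lmp-2 (370.3), lgg-2 (358), cpl-1 (299.7) and lgg-1 (290.2), and hlh-30 at 135. Oxidative stress and detoxification had 23 of 35 (65.7%, 2.59, 4.98e-07), with ftn-1, wdr-23 (315), gst-7 (295) and the superoxide dismutase gene sod-1 (292). Lipid metabolism had 34 of 53 (64.2%, 2.5, 4.55e-09), with dgat-2 (452, a peak nearer to the F-box gene fbxa-108), ech-6 (436), dhs-28 (424) and nhr-80 (375.5), but not fasn-1, fat-1 or fat-7. Heat shock and proteostasis had 24 of 38 (63.2%, 2.43, 7.53e-07), with xbp-1 (595), hsp-70 (251.5), cct-1 (249.6) and hsp-110 (245, a peak shared with the proteasome gene rpn-3), but not cct-2 or cct-4. Innate immunity had 24 of 47 (51.1%, 1.73, 0.000106), with fshr-1 (566), lys-8, lys-7 and spp-5 (409.7), but not abf-1 or abf-2. With peaks given to the nearest start only, heat shock and proteostasis no longer passed (adjusted exact p = 0.0534), and glycolysis fell to a log2 odds ratio of 2.46 in the stronger 50% of peaks. Promoter peaks of glycolysis genes had a DBE at 8 of 42, of oxidative stress genes at 6 of 28 and of heat shock genes at 2 of 25. Those of lipid metabolism had it at 1 of 54, of innate immunity at 1 of 40 and of autophagy at 0 of 37. None passed against other promoter peaks (Fisher's exact test, smallest adjusted p = 0.133), a comparison chosen after seeing the data. Open chromatin at these promoters was not tested.

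Among cell type markers, intestinal genes were bound more often than other genes, and hypodermis and cuticle genes less often. Of 34 intestine markers 25 were bound (73.5%, 56.9 to 85.4, log2 odds ratio 3.10, adjusted exact p = 9.17e-09), among them ftn-1, the intestinal GATA factor gene elt-2 (signal 383), cpr-6 (355) and eps-8 (347.5), but not aqp-8 or fat-7. Of these 34 genes, 16 also stood in other lists. Of 41 hypodermis and cuticle markers 2 were bound, semo-1 (144) and wrt-10 (39.0, without a counterpart in replicate 1), or 4.88% (1.35 to 16.14, log2 odds ratio -2.32, adjusted exact p = 0.00427). That list missed the threshold with the stronger 50% of peaks (adjusted exact p = 0.0510). Muscle markers had 6 of 44 bound, with deb-1 strongest (447, adjusted exact p = 0.177), and neuron markers 7 of 54, with unc-18 strongest (234, adjusted exact p = 0.0994). Germline markers had 11 of 56, with gld-3 strongest (188, adjusted exact p = 0.549), and gonad, vulva and excretory markers 6 of 28, with egl-17 strongest (187, adjusted exact p = 1). The neuron list passed as bound less often with the window of 500 bp upstream to 100 bp downstream (adjusted exact p = 0.0462) and without replicate 1 (0.0454).

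Large gene families differed widely. Ribosomal protein genes were bound at 63 of 78 promoters (80.8%, 70.7 to 88.0, log2 odds ratio 3.72, adjusted exact p = 7.08e-25), with rpl-3 (signal 557), rpl-12 (502), rpl-20 (463) and rpl-15 (364.5) strongest. Proteasome genes were bound at 24 of 33 (72.7%, adjusted exact p = 2.03e-08), led by rpn-3 (245), and translation factors at 26 of 39 (66.7%, 6.63e-08), led by eef-1A.2 (478). The detoxification families followed, with 37 of 67 UDP-glycosyltransferase genes (55.2%, 1.48e-07), led by ugt-50 (626), 39 of 74 cytochrome P450 genes (52.7%, 3.56e-07), led by cyp-33C7 (538), and 21 of 44 glutathione S-transferase genes (47.7%, 0.000968). Vacuolar ATPase genes had 10 of 20 bound (50%, 0.0207), led by vha-12 (272), and nuclear hormone receptor genes 93 of 269 (34.6%, 0.000134). Chemoreceptor genes were bound at 40 of 1304 (3.07%, 2.26 to 4.15, log2 odds ratio -3.41, adjusted exact p = 3.91e-102), srh-2 most strongly (742). Collagens were bound at 10 of 156 (6.41%, 3.32e-08), with col-38 strongest (212), major sperm protein genes at 1 of 31 (3.23%, 0.00733), C-type lectins at 34 of 240 (14.2%, 0.000425) and F-box genes at 61 of 322 (18.9%, 0.0487). The F-box list pooled subfamilies that differed, as given under the other observations. Histone genes, at 13 of 72 (0.289), and insulin-like peptide genes, at 6 of 39 and led by ins-39 (373, 0.288), did not pass. With nearest starts only, the log2 odds ratio fell to 2.03 for ribosomal protein genes, 1.60 for proteasome genes and 1.81 for translation factors, and in the stronger 50% of peaks to 2.85, 1.91 and 1.55, all still passing. Without replicate 1 it was 3.12 for ribosomal protein genes, without replicate 2 1.84 for translation factors, and with neighbouring members counted once -2.34 for chemoreceptor genes. The calls for C-type lectins (adjusted exact p = 0.0956) and F-box genes (0.959, and log2 odds ratio 0.04) ended when neighbouring members were counted once. That for F-box genes also ended without replicate 1 (0.221) and without replicate 2 (0.214), with the window of 500 bp upstream (0.388), with nearest starts (0.0922) and in the stronger 50% of peaks (1). That for vacuolar ATPase genes ended with nearest starts (0.0562) and without genes in more than 1 list (0.261), and insulin-like peptide genes passed as bound less often with the window of 500 bp upstream (0.00956).

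**Figure D3:**
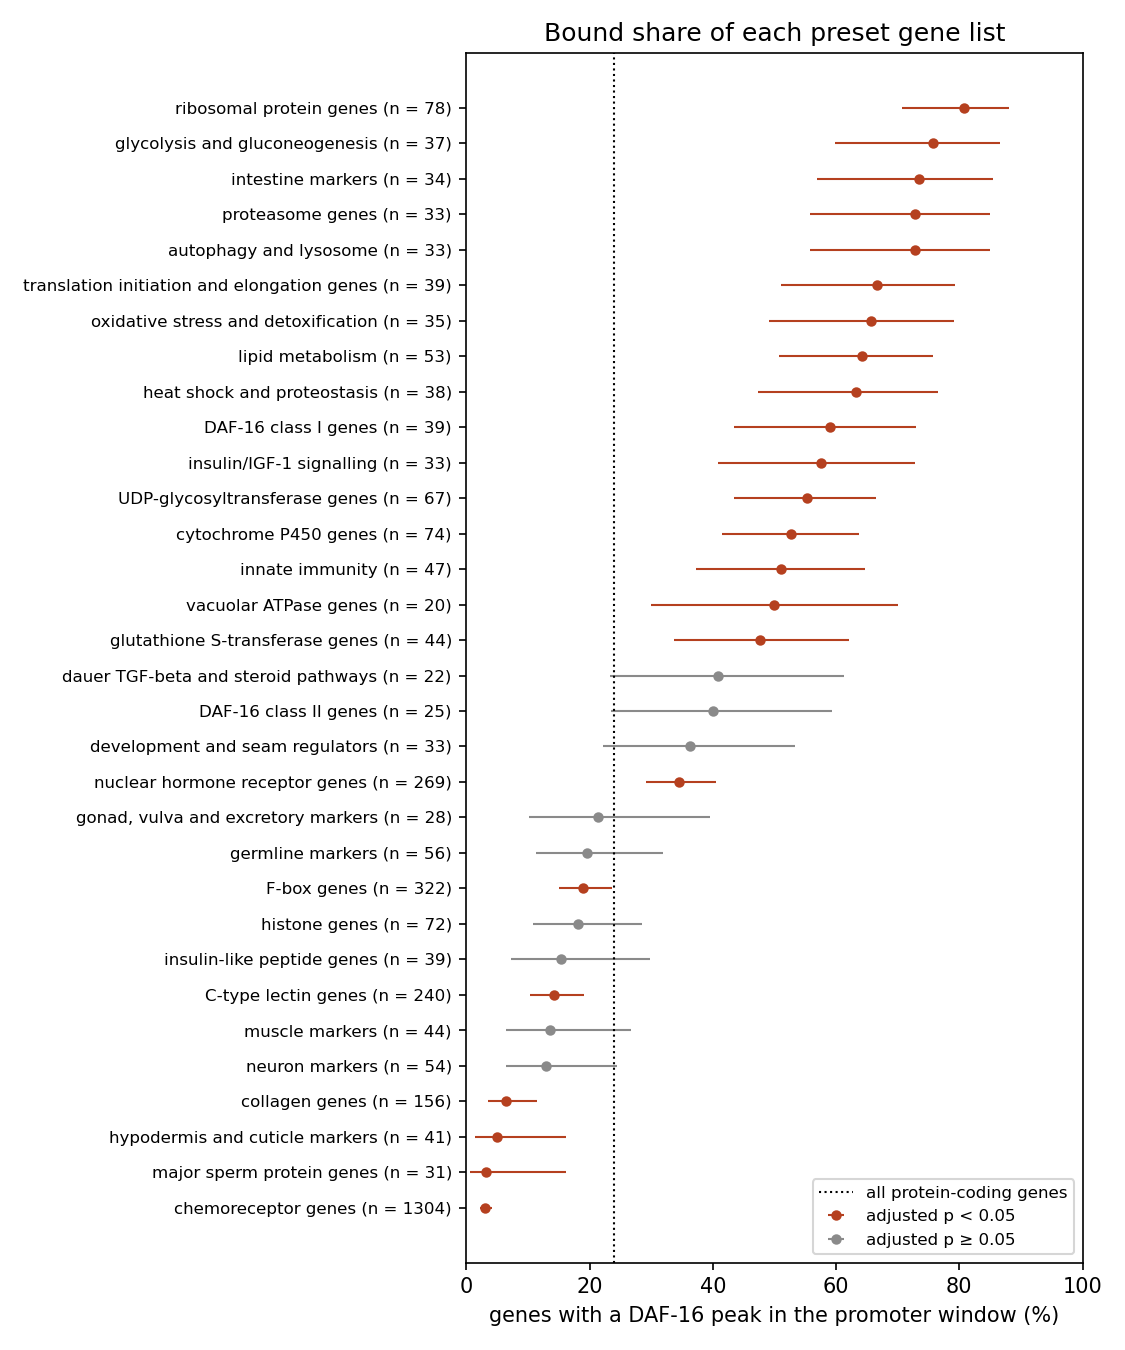
Percentage of genes of each preset list with a peak in the promoter window (points, with 95% Wilson intervals as bars and n the number of genes). Ribosomal protein genes lie highest at 80.8% and chemoreceptor genes lowest at 3.07%, with all protein-coding genes at 23.9% (dotted line).

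The DAF-16 binding element stood at DAF-16 summits, and the DAF-16 associated element and the GATA site stood at more of them. The DBE lay within 75 bp of 782 of 8748 summits (8.94%, 8.36 to 9.56), against 1.79% of sequences of the same width centred 500 bp away (log2 ratio of discordant pairs 2.43, adjusted exact p = 7.30e-104). The DAE lay at 21.8% against 3.30% (3.08), and the GATA sequence TGATAA at 42.5% against 15.4% (2.08), both with an adjusted p below 1e-300. GAGA repeats stood at 5.75% against 1.36% (2.18, 4.01e-59), the E-box CACGTG, bound by HLH-30 among others, at 6.02% against 2.73% (1.21, 5.36e-27), and the SKN-1 site at 7.40% against 5.33% (0.50, 3.36e-08). The heat shock element was less frequent at summits, 6.57% against 10% (-0.66, 3.19e-16), a call that ended against dinucleotide-shuffled summit sequences (-0.09, 0.313). The reversed DBE, a control sequence, stood at 4.07% against 3.58% (adjusted exact p = 0.109) and the reversed DAE at 2.29% against 2.13% (0.505). Tests were exact two-sided McNemar tests over peaks, adjusted over 9 motifs. The reversed DBE passed within 50 bp (0.37, adjusted exact p = 0.00854), in the stronger 50% of peaks (0.40, 0.0148) and without replicate 1 (0.47, 5.11e-05), and the reversed DAE passed against shuffled sequences (0.41, 0.0121), so differences of that size also arise for control sequences.

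Stronger peaks held the DBE more often. In the strongest quintile 313 of 1750 summits (17.9%, 16.16 to 19.8) had it, and 81 of 1749 (4.63%, 3.74 to 5.72) in the weakest (log2 odds ratio 2.16, two-sided Fisher's exact p = 4.94e-37). The quintiles between had 10.5%, 6.46% and 5.20%. The DAE went from 28% in the strongest to 12.06% in the weakest, and the GATA site from 53.8% to 29.6%, without a test of their own. The reversed DBE, compared the same way after seeing the data, had 4.40% and 3.54% (log2 odds ratio 0.32, Fisher's exact p = 0.225).

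**Figure D4:**
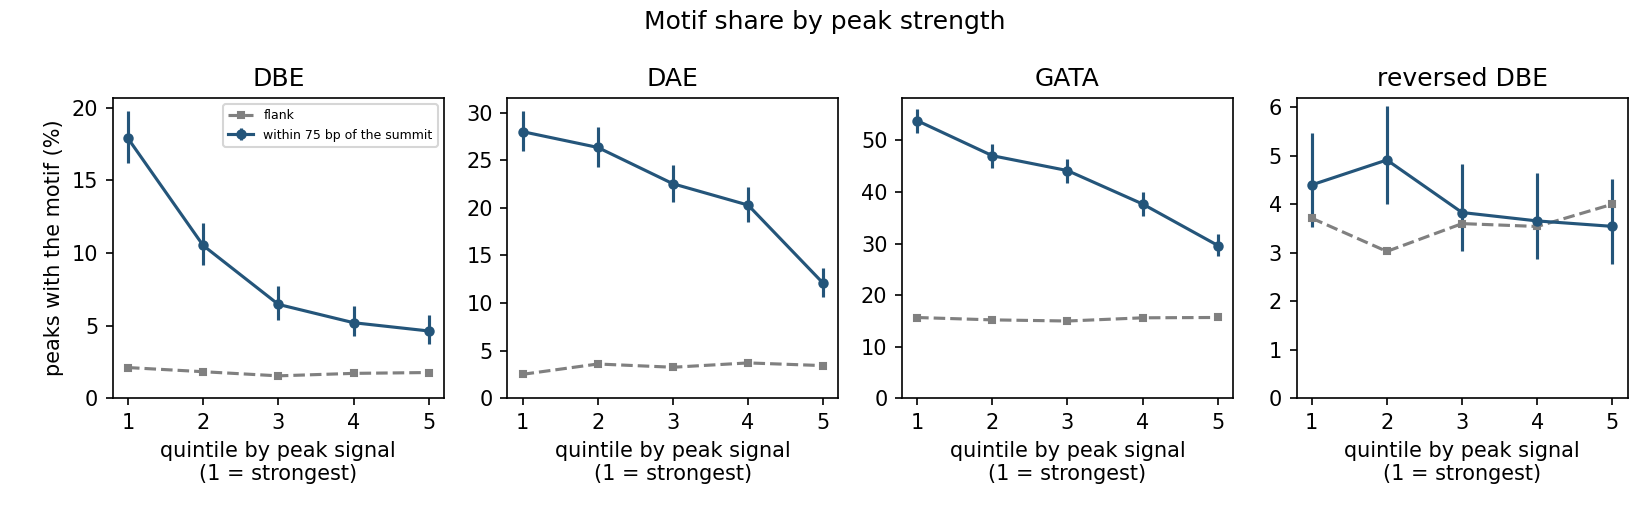
Percentage of peaks with each motif within 75 bp of the summit (circles, with 95% Wilson intervals) and in the flank (squares) for quintiles of peaks by signal, 1 the strongest. The DBE share is 17.9% in the strongest and 4.63% in the weakest, and the reversed DBE stays between 3.54% and 4.91%.

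Genes on the X chromosome were bound slightly more often than autosomal genes. Of 2731 X-linked genes 747 were bound (27.4%), and of 17242 autosomal genes 4032 (23.4%; log2 odds ratio 0.30, two-sided Fisher's exact p = 8.83e-06). By chromosome, the bound share was 30.5% on III, 24.1% on I, 23.7% on IV, 22.1% on II and 19.9% on V, so III stood above X. Peaks were densest on X, at 114 per Mb against 92.6 on III and 74.4 on I. The stronger 50% of peaks gave a log2 odds ratio of 0.70 (Fisher's exact p = 2.62e-18). Of 3 alternatives chosen after seeing the data, strata of upstream gap gave 0.47 (Mantel-Haenszel p = 5.85e-12), leaving out chemoreceptor, F-box and C-type lectin genes 0.18 (Fisher's exact p = 0.0103) and leaving out chromosome V 0.19 (Fisher's exact p = 0.00638).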

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

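The tests of whole-genome pile-up, of DBE and GATA sites at housekeeping promoters and of base composition were chosen after their results had been seen. The others were set beforehand.

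The list held 29 mitochondrial peaks, which the nuclear comparisons left out and only the overlap of replicates included. Their strongest signal was 7975.1 against 1392 for the strongest nuclear peak, and 9 of the 10 strongest peaks of the list, 9 of 10 in replicate 1 and 10 of 10 in replicate 2 were mitochondrial. Called regions covered 99.0% of the 13794 bp genome, as read pile-up over a multi-copy genome would. Forkhead sites in the mitochondrial genome stay open, since 1 of the 29 summits had a DBE within 75 bp, against a median of 1 and a 95th percentile of 2 after circular shifts. The count was set to speak against them at or below the median, but with 3 DBEs in this genome it could hardly differ from chance. The control library was not analysed here.

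Ribosomal protein, translation factor and proteasome promoters were bound at 113 of 150 genes. Random gene sets matched on promoter GC content gave a mean of 37.9 bound (central 95% 28 to 48), which argues against GC content as the cause. Of the peaks there, 7.56% (4.03 to 13.8) had a GATA site against 42.5% of all peaks and 13.4% of their flanks, which argues against GATA sites. A DBE stood at 4.202% (1.81 to 9.46) against 0.840% of flanks (exact McNemar p = 0.219), an interval that includes the 8.94% of all peaks, so the count is too small to decide on forkhead sites. Open chromatin or high transcription drawing any tagged protein may also account for these peaks and was not tested, since no tag-only library or accessibility data were analysed here.

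The DBE share fell with peak strength. Less exact summits in weak peaks are argued against, because the flank-corrected share within 150 bp was 5.10 times higher in the strongest than in the weakest quintile (bootstrap 95% range 3.53 to 8.77). Base composition is argued against by the reversed DBE, whose ratio was 1.24 against 3.86 for the DBE. In the weakest quintile 45.2% had a peak of both replicates within 100 bp, under the level set beforehand for false calls. Weak real sites could also be missing from a replicate's list, so this share cannot tell them from false calls. Peaks absent from a replicate do not account for all of it, because the ratio was 3.46 (2.64 to 4.98) among peaks found in both replicates. Weak peaks found in both had a DBE at 5.19% against 2.15% of flanks (exact McNemar p = 0.00184). Those not found in both had it at 4.17% against 1.46% of flanks (exact McNemar p = 0.000535). The replicates' full lists include background regions, so false calls can match in both. Whether false calls cause any of the fall stays open.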

How the results depend on the processing

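The share of replicate 1's peaks found in replicate 2 was 75.4% with intervals overlapping by at least 1 bp, 53.8% with 50% of both, 72.5% for the stronger 50% of the peaks and 49.4% for all peaks, as the definitions differ; the ce10 lists gave 64.3%. The share of summits in promoters was 40.3% with the window of 500 to 100 bp, 69.3% with that of 2000 to 500 bp and 55.7% for the stronger 50% of peaks, each above every shift. The stronger 50% of peaks left 2687 bound genes. The pooled list gave the same peaks, so it tested nothing. The number of lists passing, 23 of 32, ranged from 21 to 25 over the alternatives, with 17 to 19 bound more often and 4 to 7 less often. Of 288 list results under an alternative, the pooled list left out, 261 kept direction and side of the threshold, 9 lost the call in the same direction and 12 gained one. The 6 that changed sign, none of which passed and of which those of F-box genes also lost the call, were gonad, vulva and excretory markers with the 500 bp window (log2 odds ratio 0.0058), the stronger 50% of peaks (0.24) and matched lists (0.088, a log2 ratio of counts), F-box genes with the stronger 50% of peaks (0.0013) and with neighbours counted once (0.044), and histone genes with neighbours counted once (0.93). Larger log2 odds ratios arose for class I genes (2.91) and innate immunity (2.39) in the stronger 50% of peaks, for intestine markers (4.40) without genes in other lists, and, further below 0, for hypodermis markers (-4.28) and major sperm protein genes (-3.88) with the 500 bp window. The reversed DBE changed sign against shuffled sequence (-0.21) and the reversed DAE within 50 bp (-0.17) and without replicate 1 (-0.17; without replicate 2, 0.074). The cause was not tested. The contrast of the DBE between quintiles passed in 5 alternatives set beforehand (log2 odds ratio 1.36 to 2.86), and the reversed DBE, added after seeing the data, gave 0.32. Excess binding of X-linked genes passed in all 8 alternatives other than the pooled list. Unknown read depth limits all counts of peaks.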

Other observations

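The comparisons below were all chosen after seeing the data, and no separate data were used to test what they showed.

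Non-coding RNA genes of every class tested were near DAF-16 peaks more often than after shifts. Of 612 tRNA genes, 63.7% had a summit from 1000 bp upstream to 300 bp downstream of their start, against a mean of 10.9% and a highest value of 16.18% over 1000 circular shifts. Small nucleolar RNA genes had 45.1% against 9.78%, small nuclear RNA genes 28.7% against 9.33%, lincRNA genes 25.3% against 10.1%, microRNA genes 23% against 10.4% and other ncRNA genes 17.6% against 10.5%. Pseudogenes had 6.53% against 9.59%. Each two-sided permutation p was 0.002, the smallest possible, and genes that share a cluster or a neighbouring coding promoter were counted separately. Accessible chromatin at these genes was not tested, since no tag-only library or accessibility data were analysed here, so the shares do not separate DAF-16 binding from it.

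Families grouped by the shared part of their names were tested for 117 families of at least 15 members, with two-sided Fisher's exact tests and Benjamini-Hochberg adjustment. Bound more often were 22 and bound less often 39. Beyond the preset lists, carboxylesterase-domain genes (cest) had 20 of 32 bound (log2 odds ratio 2.39, adjusted exact p = 3.19e-05), dehydrogenase genes (dhs) 19 of 30 (2.44, 3.93e-05), aspartyl protease genes (asp) 11 of 17 (2.49, 0.00167), vacuolar sorting genes (vps) 16 of 31 (1.76, 0.00348) and nuclear pore genes (npp) 13 of 26 (1.67, 0.0117). Neuropeptide genes (nlp) had 3 of 71 (-2.63, 0.000107), ligand-gated channel genes (lgc) 2 of 56 (-2.78, 0.000310) and neuropeptide receptor genes (npr) 1 of 43 (-3.16, 0.000917). Transthyretin-related genes (ttr), which had 3 of the 20 strongest promoter peaks by nearest start, had 14 of 58 bound and did not differ from other genes (0.05, adjusted exact p = 1).

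Promoter peaks of different lists held different motifs, with 14 of 96 combinations of list and motif passing a two-sided Fisher's exact test after adjustment. A DBE stood at 9 of 29 class I promoter peaks (31.03%, 17.3 to 49.2) and at 8.92% of the 4664 other promoter peaks (adjusted exact p = 0.00872). GATA sites stood at 11 of 12 class II promoter peaks (91.7%, adjusted exact p = 0.00449), 82.4% of those of C-type lectins (1.77e-05), 70% of those of innate immunity genes (0.00282), 64.4% of those of F-box genes (0.00379), 63.9% of those of intestine markers (0.0409) and 61.7% of those of chemoreceptor genes (0.0318), against 39.9% to 40.03% of the other promoter peaks. These tests did not correct for local sequence, and the flanks had a GATA site at 34.04% of chemoreceptor, 23.5% of C-type lectin and 20.3% of F-box peaks, against 15.4% over all peaks. GATA sites were less frequent at peaks of ribosomal protein genes (4.69%, adjusted exact p = 6.94e-09), translation factors (10.3%, 0.00913) and proteasome genes (11.1%, 0.0129). The DAE stood at 58.8% of C-type lectin peaks (4.04e-05) but at 0 of 64 peaks of ribosomal protein genes (1.77e-05), 0 of 29 of translation factors (0.0175) and 4.76% of those of glycolysis genes (0.0460). A DAE was less frequent at summits with a DBE than at others, 18.3% against 22.2% (odds ratio 0.785, two-sided Fisher's exact p = 0.0111), and 52% of summits had none of DBE, DAE and GATA site. Among all 7-mers, ACGCAGA and CTGCGTC, which belong to no preset motif, stood at 7.70% and 7.49% of summits against 1.57% and 1.5% of flanks. The reverse complement of CTGCGTC, GACGCAG, overlaps ACGCAGA, so both can mark the same sites.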
